A study of Mus musculus with 6 samples.

How the data were processed

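Polyadenylated RNA from femoral bone was extracted with TRIzol and made into strand-specific libraries with the NEBNext Ultra Directional kit, per the labels' protocols. The submitters' processing notes name Trimmomatic 0.39, HISAT2 2.2.1, SAMtools 1.10, Cufflinks 2.2.1 and genome build GRCm38, without roles or settings. Whether the counting used strand is not given in the sources used here, so overlapping antisense genes could share fragments.

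Both tables hold 55484 genes, and their columns and status words are those of Cuffdiff, the comparison program of Cufflinks, per the file headers. The authors deposited 1 FPKM per group with the lower and upper bound of an interval whose level the headers do not state. The authors also deposited a log2 fold, a test score (the test statistic), and a p-value and q-value per gene. The smallest p-value in the authors' deposited table is 5e-05, so many genes tie at the smallest q. The deposited q matched a Benjamini-Hochberg adjustment of p over the tested genes, with a largest difference of 5.21e-07. Of the genes, 15508 were tested by the authors, 39971 have the status NOTEST, and 5 have the status HIDATA and are listed at 0 in 1 or both groups (Col1a1, Col1a2, Hbb-bs, Hba-a1 and Gm43921). These 5 were left out of totals and tests. For 7 genes listed at several loci the 2 tables give different FPKM, and the comparison table was used.

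With 0 columns of single libraries, no test between mice could be made here and no spread between mice is known. The authors' q-value under 0.05 among tested genes was therefore taken as the call, as set before the data were examined for tables of this kind. Replicates are separate mice per the study's design text. How fragments that match several genes were treated is not given in the sources used here, so genes with close copies or overlapping neighbours could trade fragments.

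From the group values, log2 folds were computed on the log2(FPKM + 0.1) scale, which understates the change of low genes. The 35 gene lists were fixed before the data were examined: osteocyte markers, osteoblast and bone matrix, osteoclast, chondrocyte, CCN family, YAP and TAZ targets, immediate early genes, mechanosensing, Wnt ligands and targets, BMP and TGF-beta, insulin and IGF signalling, glucose uptake and glycolysis, TCA cycle and respiration, skeletal muscle, slow muscle fibre, adipocyte, erythroid, neutrophil, B lineage, plasma cell, T and NK cell, monocyte and macrophage, mast cell with basophil and eosinophil, megakaryocyte, endothelial, marrow stroma, tendon with periosteum and fibroblast, nerve and Schwann cell, cell cycle, interferon response, inflammatory cytokines, circadian clock, glucocorticoid and metallothionein, heat shock, and hypoxia and angiogenesis. In the lists, 1 symbol had no match; of several IDs with 1 symbol, the most expressed was used. For each list and direction, a two-sided Fisher's exact test compared called and uncalled members against the 14488 tested genes with FPKM of at least 1 in at least 1 group, with Benjamini-Hochberg adjustment over 70 tests. This test treats genes as independent, so its p describes the pooled values of these libraries and not the spread between mice. Calls were also made with q adjusted over the list alone. List medians were placed among 10000 random lists matched on mean FPKM in 20 bins; since genes of a cell type move together, this percentile only describes these libraries. On simulated folds for the 14488 genes of the comparison of wheel running with sedentary mice, the same list code placed 4 of 4 lists shifted by 0.5 (log2), and 2 of 31 lists not shifted, outside the central 95% of random lists. The simulated folds were independent between genes, so this does not show how often lists of genes that move together fall outside. The shift was larger than the median of every real list but the adipocyte list (0.54).

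The genes named were chosen by a rule set before the data were examined. It took the CCN family, the 12 largest log2 folds in each direction among calls with FPKM of at least 1 in a group, called members of the lists discussed (the 4 largest where more were called) with up to 2 uncalled members, and the 5 most expressed genes above 2000 FPKM. Predicted genes, immunoglobulin and T cell receptor segments and small RNAs were counted instead; the immunoglobulin genes, Gapdh, Aldoa, Uqcrc2 and the fifth glucocorticoid gene, Fkbp5, were named after their values were seen, as were B430306N03Rik and uncalled members beyond the allowed number. Coordinates are those of GENCODE vM21 on GRCm38, matched by Ensembl ID for 55224 of the 55484 genes.

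Library totals are not given in the sources used here. Relative depth was read from single-exon, single-transcript genes longer than 1500 bp, in which the lowest FPKM multiplied by length fell into 3 steps per group. Lengths were shortened by 250 bp in the sedentary and 255 bp in the running group, the values at which the lowest products varied least, and the range searched for steps was chosen after the values were seen. Which step belongs to which mouse is unknown.

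Alternatives covered the q threshold, low-FPKM filters, a minimum fold, gene classes, 3 scalings between groups, the pseudocount, the enrichment background and the list members. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.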

Results

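RNA from femoral bone of male wild-type C57BL/6 mice was sequenced in 6 libraries, 3 from sedentary mice and 3 from mice that had free access to a running wheel. All 6 sample titles begin with ND, a label that both groups share. The mice entered the groups at 6 weeks of age, lived singly for 6 weeks and were 12 weeks old when the bones were taken. The comparison asks which transcripts of the femur differ after voluntary running, and the title of the study points to osteocytes, glucose metabolism and the matricellular protein CCN1. Femoral bone holds osteocytes, osteoblasts and, unless flushed, marrow. The labels used here do not say how marrow, muscle or periosteum were handled. Neutrophil genes were among the most expressed (S100a9 at 20406 FPKM in sedentary and 17115 in running mice), so marrow or blood cells contributed to the RNA. Each gene has 1 pooled FPKM per group (fragments per kilobase of transcript, scaled to the number of fragments) with the bounds of the authors' interval, so no SD between mice can be given and every call below is the authors'. Unless stated otherwise, log2 folds are wheel running over sedentary on the log2(FPKM + 0.1) scale, computed here from the group values, and a gene is called when q in the authors' deposited table lies under 0.05. The size of 1 fragment in the lowest FPKM values gave rounded effective depths of 16400000, 14500000 and 14300000 fragments for the sedentary libraries and of 17400000, 17200000 and 13800000 fragments for the running libraries, an estimate that assumes that a group value is the mean of 3 scaled libraries. Among genes with FPKM of at least 10, the median half-width of the authors' interval was 26.3% of the FPKM in sedentary and 26.1% in running mice.

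Ccn1 was higher in the running mice. Ccn1 (ENSMUSG00000028195; chromosome 3, 145646976 to 145649981, minus strand, GRCm38) encodes a secreted matricellular protein and is a target of the YAP and TAZ coactivators. The authors' FPKM was 81.3 (interval 66.2 to 96.4) in sedentary mice and 114 (93.0 to 134) in running mice, a 1.40-fold difference and a log2 fold of 0.48. In the authors' deposited table its q was 0.00718, the smallest value the table holds, shared by 108 genes. The 2 intervals overlapped slightly. Of the other CCN genes, none was called. Ccn2 stood at 80.1 and 104 FPKM, and its q in the authors' deposited table was 0.0798. Ccn3 had FPKM of 1.51 and 2.01, Ccn4 of 30.4 and 35.1, and Ccn5 of 18.5 and 14.8, in sedentary and running mice respectively. Ccn6, at 0.227 and 0.319 FPKM, was not tested by the authors. Adjusted over the list alone, 2 of the 5 measured CCN genes were called higher and 1 lower.

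**Figure D1:**
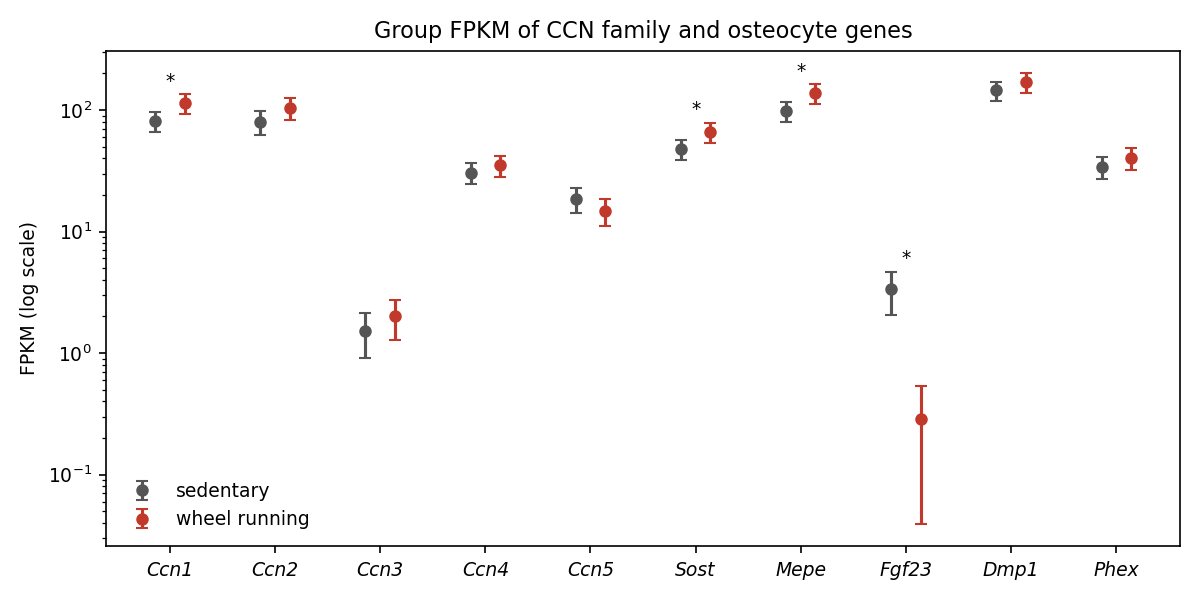
Authors' group FPKM (log axis) of CCN family and osteocyte genes in sedentary (grey) and wheel running (red) mice; bars are the authors' intervals and asterisks mark calls. Ccn1, Sost and Mepe were called higher and Fgf23 lower, from 3.36 to 0.288 FPKM.

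Across the 15508 genes the authors tested, 146 were called, 69 higher and 77 lower in running mice. The median log2 fold of the calls was 0.63 for those higher and -1.58 for those lower, and -0.85 for the lower calls outside the immunoglobulin genes. Immunoglobulin genes made up 42 of the lower calls and 1 of the higher calls. Outside the immunoglobulin loci 68 genes were higher and 35 lower. At an unadjusted p under 0.05 the authors' deposited table held 876 genes, where 775 would be expected by chance. The authors' intervals of the 2 groups overlapped for 77 of the 146 called genes, and 69 calls, 19 higher and 50 lower, had intervals apart. The deposited test statistic was under 1.96 in size for 10 of the calls, although their q in the authors' deposited table passed the threshold. That cut is the normal value for a p of 0.05, looser than the p of any call, so it marks only the largest mismatches. Ccn1 had a test statistic of 2.58 at the smallest p in the authors' deposited table, where a normal score would be larger. How the authors' p follows from the statistic is not given in the sources used here.

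**Figure D2:**
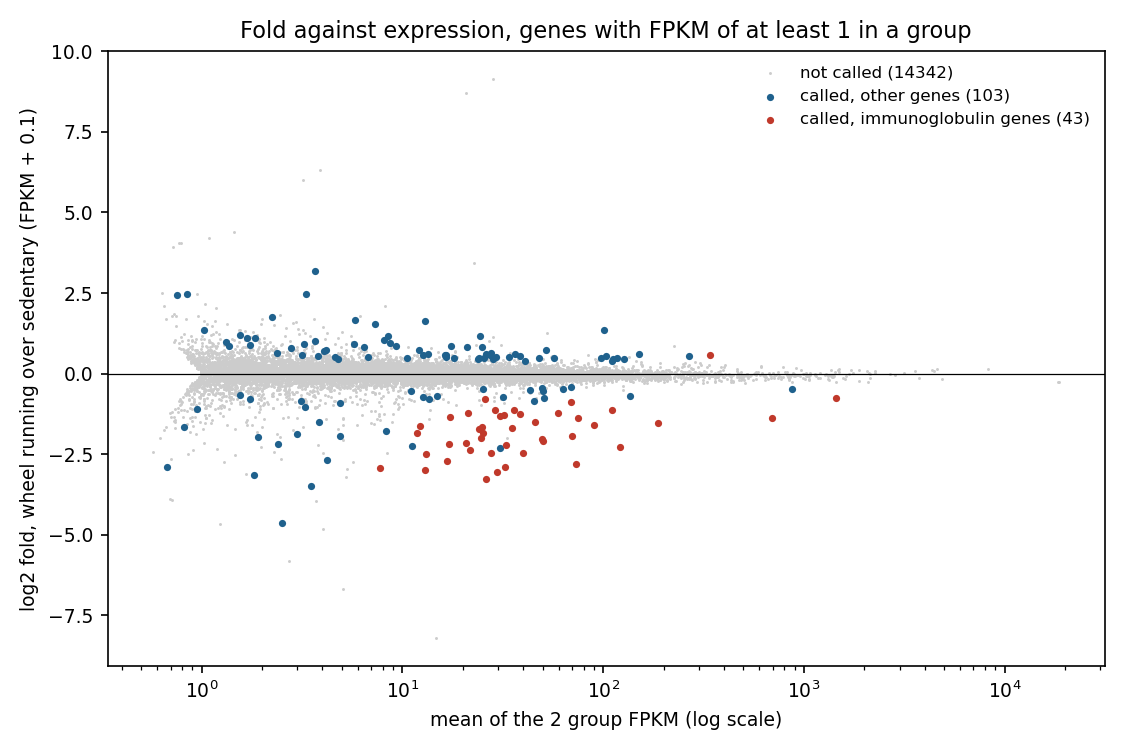
Log2 fold (FPKM + 0.1) against the mean of the 2 group FPKM (log axis) for 14488 genes with FPKM of at least 1 in a group. Of the called genes, 43 were immunoglobulin genes (red), 42 of them lower in running mice, and 103 were other genes (blue).

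Called osteocyte genes moved in both directions. Of 13 measured osteocyte markers, 11 had a positive log2 fold. The calls were 2 higher and 1 lower, and the higher calls were an enrichment (adjusted p = 0.0197, Fisher's exact test). Neither higher call had separate intervals. Sost (chromosome 11, 101962458 to 101967015), which encodes the Wnt antagonist sclerostin, rose from 47.4 to 66.2 FPKM, and Mepe (chromosome 5, 104325329 to 104338611), which encodes a matrix phosphoglycoprotein, from 98.4 to 137 FPKM. Fgf23 (chromosome 6, 127072902 to 127081408), which encodes a phosphate-regulating hormone, fell by 3.16 on the log2 scale, from 3.36 (2.05 to 4.68) to 0.288 (0.0395 to 0.536) FPKM. Dmp1, at 145 and 169 FPKM, and Phex, at 34.0 and 40.4 FPKM, did not pass the test. The median log2 fold of the osteocyte list was 0.25, at percentile 99.98 of expression-matched random lists. Over the list alone, 3 members were called higher and 1 lower. Among 16 measured osteoblast and matrix genes, Cthrc1 alone was called, higher, at 0.966 and 3.50 FPKM with overlapping intervals; the list median was 0.17, and 1 member was called higher when adjusted over the list alone. Alpl stood at 84.9 and 102 FPKM and Ibsp at 562 and 666 FPKM, both uncalled. Col1a1 and Col1a2 have no estimate in either group and were left out. None of 14 osteoclast genes was called (median 0.08), nor of 15 chondrocyte genes (median 0.03, and -0.04 over members with FPKM of at least 5). In the same libraries the median log2 fold was 0.29 for skeletal muscle genes, 0.54 for adipocyte genes, 0.23 for marrow stroma genes and -0.17 for neutrophil genes.

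Targets of YAP and TAZ were enriched among the higher calls, 3 of 20 measured members (adjusted p = 0.00156, Fisher's exact test). They were Ccn1, Igfbp3, which rose from 13.6 to 19.3 FPKM, and Ankrd1, which rose from 0.899 to 2.19 FPKM. The list median was 0.19, and 5 members were called higher when adjusted over the list alone. Tgfb2 (2.61 and 3.89 FPKM) and Amotl2 (9.17 and 11.1 FPKM) were not called over all genes. Muscle also expresses Ankrd1. In the same libraries the median log2 fold was 0.29 for skeletal muscle, 0.54 for adipocyte, 0.22 for tendon, periosteum and fibroblast and 0.23 for marrow stroma genes, and 0.19 over 130 genes of 10 non-blood lists pooled. Igfbp3 counts again in the insulin and IGF list, where it and Igfbp6 (9.13 to 15.1 FPKM), both binding proteins of insulin-like growth factors, were the 2 higher calls among 15 members (adjusted p = 0.0226, Fisher's exact test; median 0.06). Over that list alone, 4 members were called higher and 1 lower. Igf1, at 16.8 and 19.0 FPKM, and Insr, at 11.4 and 12.6 FPKM, were not called.

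No gene of glucose uptake and glycolysis was called among 23 measured, with a median log2 fold of -0.06 at percentile 10.4 and no member called over the list alone. Slc2a1, a glucose transporter, stood at 5.20 and 5.06 FPKM, a difference that changed sign when the groups were rescaled to the same total, and Ldha at 277 and 265 FPKM. Gapdh was listed at 6.83 and 7.29 FPKM, far under Aldoa at 476 and 497 FPKM; it has many pseudogenes and its value is uncertain. Among 20 measured genes of the TCA cycle and respiration, Pdk4 and Uqcrc1 were called higher (adjusted p = 0.0313, Fisher's exact test), as they were when adjusted over the list alone, while the list median was -0.02 and changed sign when the groups were rescaled to the same total. Pdk4, an inhibitor of pyruvate dehydrogenase, rose from 20.2 to 27.4 FPKM and also counts in the glucocorticoid list. The median log2 fold in these libraries was 0.29 for skeletal muscle and 0.54 for adipocyte genes. Uqcrc1, a subunit of respiratory complex III, rose from 2.72 to 8.88 FPKM, far below Uqcrc2 of the same complex at 77.1 and 73.6 FPKM. With q under 0.01 this list was no longer enriched (adjusted p = 0.275, Fisher's exact test).

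Some transcripts of muscle, fat and connective tissue were called higher in the running mice, but none of the 10 listed slow muscle fibre genes. All 19 skeletal muscle genes had a positive log2 fold, and Tcap, Myh2 and Myh1 were called (adjusted p = 0.00156, Fisher's exact test). Myh1, a fast myosin heavy chain, rose from 28.6 to 44.1 FPKM, Myh2 from 31.1 to 45.9 and the sarcomere protein gene Tcap from 94.95 to 130. Tnnt3, at 366 and 445 FPKM, and Acta1, at 278 and 336 FPKM, were not called. The rise was uneven within the list: the authors' deposited log2 fold was 0.04 for Myl1 and 0.09 for Pvalb, both uncalled, against 0.62 for Myh1. None of 10 slow fibre genes was called (median 0.00081, and -0.02 over members with FPKM of at least 5), and 5 had a positive log2 fold. Their authors' deposited log2 folds ran from -0.34 (Myl3) to 0.38 (Mb). Of 11 adipocyte genes, Adipoq, Fabp4 and Cfd rose (adjusted p = 0.000581, Fisher's exact test). Fabp4, a fatty acid carrier, went from 220 to 319 FPKM, Adipoq from 40.2 to 55.8 and Cfd from 39.0 to 64.8; Lpl (34.5 and 43.4 FPKM) was not called. Of 13 tendon, periosteum and fibroblast genes, Thbs4 rose from 12.4 to 22.6 FPKM, Tnxb from 1.13 to 2.55 and Fmod from 24.2 to 34.4 (adjusted p = 0.000667, Fisher's exact test; median 0.22). Adjusted over each list alone, 6 muscle, 5 adipocyte and 3 tendon genes were called higher.

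Of the glucocorticoid-responsive genes, 5 of 11 members were higher (adjusted p = 6.69e-08, Fisher's exact test; median 0.39). With q under 0.01, 2 were left (adjusted p = 0.00973, Fisher's exact test), and the p was larger than those of the adipocyte, tendon and YAP and TAZ lists. The adipocyte list in the same libraries had a higher median, 0.54. The 4 with the largest folds were Klf9 (15.02 to 21.1 FPKM), Cdkn1a (21.3 to 29.7), Tsc22d3 (106 to 147) and Pdk4, which also counts in the TCA list. Fkbp5, the remaining call, is among the 10 calls with a small test statistic. Sgk1 (32.3 and 41.6 FPKM) and Mt1 (177 and 205 FPKM) were not called over all genes, and 7 members were called over the list alone. In all, 8 lists were enriched among higher calls and 1 among lower calls in 70 tests. These exact tests treat genes as independent, although genes of a cell type move together, and do not measure the spread between mice. When only calls with separate intervals were kept, 1 enrichment of the 9 was left, that of tendon, periosteum and fibroblast genes.

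Immunoglobulin transcripts were lower in the running mice. Of 185 V segments tested, 35 were called lower and none higher, with a median log2 fold of -0.82. Of 11 constant genes tested, 7 were called lower and 1 higher. Ighm fell from 1001 to 385 FPKM, Igkc from 1815 to 1073 and Ighg2c from 23.2 to 2.86, whereas Igha rose from 273 (221 to 325) to 406 (331 to 481). Many V segments are near-identical, so their single values are uncertain. Jchain, which encodes the joining chain of secreted IgM and IgA, fell from 169 to 104 FPKM. It was the 1 lower call among 9 plasma cell genes, with Igha the 1 higher call (median -0.18). Adjusted over the list alone, 3 plasma cell genes were called lower and 1 higher, and with q under 0.1 the list was enriched among lower calls (adjusted p = 0.0137, Fisher's exact test). None of 15 B lineage genes was called (median -0.15), and 1 was called lower when adjusted over the list alone. In the same libraries neutrophil genes had a median of -0.17, with a positive log2 fold in 0 of 17.

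Among the 12 largest folds in each direction outside immunoglobulin and predicted genes, the highest were Hspa4l (log2 fold 3.18), D7Ertd443e (2.47), Rnf181 (2.47), Treml4 (2.44), Cthrc1 (1.76), Uqcrc1 (1.67), Mrps23 (1.63), Nfya (1.55), Nrd1 (1.36), Ankrd1 (1.20), Cyp2e1 (1.17) and Fmo2 (1.16). The lowest were Cacnb4 (-4.62), Fgf23 (-3.16), Adam3 (-2.90), Pld4 (-2.67), H2-Q5 (-2.30), Trem3 (-2.18), Treml1 (-1.97), Cish (-1.94), Plk4 (-1.88), Pstpip2 (-1.79), Syne4 (-1.65) and Pot1b (-1.4997). Cish, a cytokine-induced inhibitor of STAT5 signalling, fell from 7.80 to 1.96 FPKM, and Nrd1, a metalloendopeptidase, rose from 56.9 to 146 FPKM. H2-Q5 fell from 51.1 to 10.3 FPKM and has close MHC paralogs with which it could share fragments. Of these 24 genes, Cacnb4, Adam3, Plk4, Syne4, Treml4 and D7Ertd443e are among the calls with a small test statistic. Hspa4l and Plk4 are adjacent on chromosome 3, and Trem3, Treml4, Treml1 and Nfya lie together on chromosome 17.

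**Figure D3:**
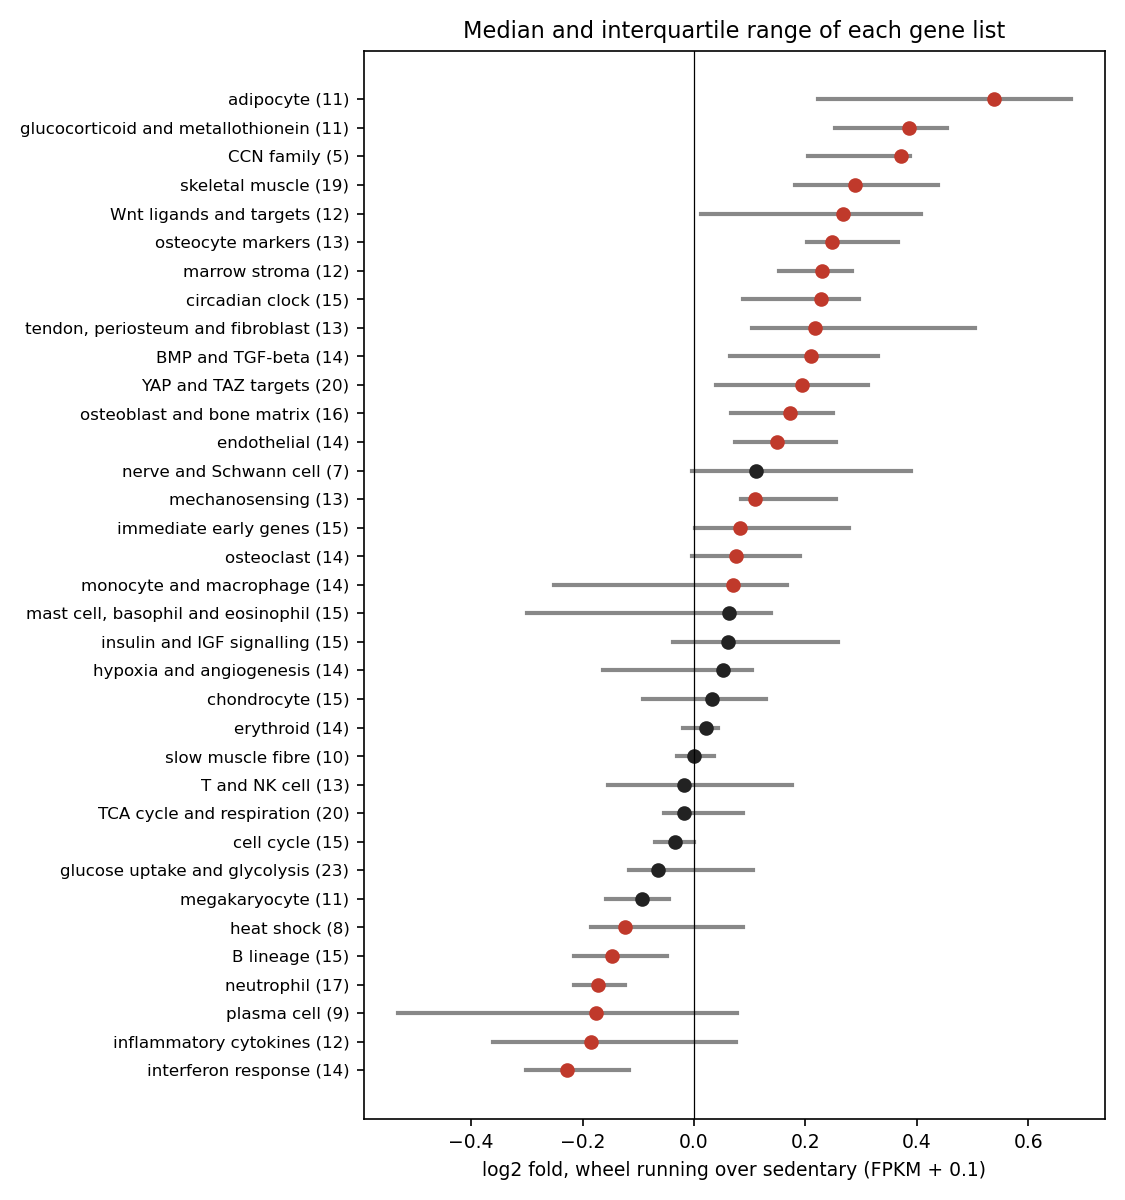
Median (point) and interquartile range (bar) of the log2 fold for 35 gene lists, with the number of measured members in parentheses; red points lie outside the central 95% of expression-matched random lists. The adipocyte list had the highest median (0.54) and the interferon list the lowest (-0.23).

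Above 2000 FPKM stood 20 genes, with the 5 HIDATA genes left out of this count and of the totals. They held 16.5% of the total FPKM in sedentary and 15.6% in running mice, counting in each group the genes above the limit there. Leaving out the 5 HIDATA genes, whose rank is unknown, the 5 highest were S100a9 (20406 and 17115 FPKM), S100a8 (20105 and 16793), mt-Co1 (7866 and 8647), Ngp (5155 and 4572) and Hbb-bt (4381 and 4870).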

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

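The alternatives that keep calls with a test statistic of at least 1.96 in size, calls with separate intervals, or calls without a near neighbour were chosen after seeing the data; the others were set before. No paired analysis was possible because the tables hold 1 pooled value per group and no column carries a replicate number. For the same reason leaving out single libraries, other splits of the libraries and the planned fits on single libraries were not run, and a single mouse behind a call could not be detected. The count of 146 called genes (69 higher, 77 lower) lay within 1.5 times its value under 6 of the 9 alternatives that could change it. The other 4, the 3 scalings and the filter at FPKM of 1 with the deposited q, could not: the scalings shift all folds alike by at most 0.05 and the smallest called log2 fold was 0.38 in size, while the filter removed no call. A minimum absolute log2 fold of 1 left 72 genes, 17 higher and 55 lower. Without predicted, immunoglobulin and T cell receptor genes 97 were left, 65 higher and 32 lower, which raised the share of higher calls from 47.3% to 67.0%. Separate intervals left 69, 19 higher and 50 lower. These 3 changes follow from the genes each setting removes. The settings within 1.5 times also reuse the authors' deposited test, most of them by keeping a part of the same calls. They are therefore no separate test of the calls. The 9 enrichments numbered 7 with q under 0.01 and 12 with q under 0.1, and 1 with separate intervals, a stricter demand than a test at the same level. The log2 fold of Ccn1 ranged from 0.48 to 0.53 and its recomputed q was 0.00671. Among uncalled genes the report names, Slc2a1 turned from -0.04 to 0.00077 when rescaled to the same total. Of 140 alternative list medians with another pseudocount or other members, 133 stayed on the same side of the central 95% of random lists, 3 moved inside it and 4 moved outside it. Rescaling to the same total raised log2 folds by 0.04 and turned the medians of the TCA, T and NK cell and cell cycle lists from below to above 0. Depth limits low genes: intervals of genes such as Adam3 and Treml4 reach 0 in at least 1 group.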

Other observations

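The tests of explanations in the last 3 paragraphs were chosen after the results were seen; the gene lists were set before. Basophil protease genes fell in running mice: Mcpt8 from 51.0 to 35.5 FPKM and Prss34 from 78.8 to 58.9, 2 of 15 measured mast cell, basophil and eosinophil genes (adjusted p = 0.0245, Fisher's exact test; list median 0.06); adjusted over the list alone, 3 were called lower. Eosinophil members such as Prg2 (937 and 1009 FPKM) were not called, and the enrichment was lost with q under 0.01 (adjusted p = 0.275, Fisher's exact test). In the monocyte and macrophage list (median 0.07) Cd163, a scavenger receptor of tissue macrophages, rose from 20.01 to 28.0 FPKM and Ccr2, a chemokine receptor of inflammatory monocytes, fell from 57.3 to 42.2; adjusted over the list alone, 1 was called higher and 1 lower. Il1b fell from 15.8 to 9.48 FPKM, the 1 call among 12 inflammatory cytokine genes (median -0.19). Adjusted over the list alone, 3 of them were called lower, and with q under 0.1 the list was enriched among lower calls (adjusted p = 0.0216, Fisher's exact test). Interferon response genes had the lowest list median (-0.23) with no call, over all genes or adjusted over the list alone, and Isg15 stood at 90.6 and 73.6 FPKM. In the same libraries the median was -0.17 for neutrophil genes, below every random list and with a positive log2 fold in 0 of 17, and -0.15 for B lineage genes. In the marrow stroma list (median 0.23) Lepr, the leptin receptor of stromal cells, rose from 27.9 to 39.7 FPKM, a call with a small test statistic and the 1 call among 12 members (adjusted p = 0.271, Fisher's exact test); adjusted over the list alone, 2 were called higher.

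Circadian clock genes had a median of 0.23 with no call; Per1 stood at 22.7 and 30.4 FPKM, while Arntl stood at 7.77 and 7.80. Medians with no call were 0.27 for Wnt ligands and targets, 0.21 for BMP and TGF-beta, 0.15 for endothelial, 0.11 for mechanosensing, 0.11 for nerve and Schwann cell, 0.08 for immediate early, 0.05 for hypoxia and angiogenesis, 0.02 for erythroid and -0.12 for heat shock genes. They were -0.02 for T and NK cell and -0.03 for cell cycle genes, both above 0 when rescaled to the same total. Adjusted over the list alone, 1 nerve and Schwann cell and 1 heat shock gene were called higher, and no member of the other lists named so far in this paragraph was called. The megakaryocyte median was -0.09, with Treml1 called lower, the 1 call also when adjusted over the list alone. Treml1 lies within 100 kb of Nfya, which was called higher, so a different assignment of fragments between neighbours may be the source. The CCN family median was 0.37. For comparison, the median was 0.19 over the pooled genes of the non-blood lists, 0.29 for skeletal muscle and 0.54 for adipocyte genes. In all, 17 of 35 list medians lay above and 6 below the central 95% of random lists.

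Immunoglobulin transcripts were lower, with a median log2 fold of -0.82 over 193 measured genes. A general loss of B lineage cells is argued against by that list's median of -0.15 (25th percentile -0.21), and trading of fragments between similar V segments by 7 constant genes called lower of 11 tested and no V segment called higher. A loss of plasma cells of every class alike is argued against by the rise of Igha (log2 fold 0.57); the 7 plasma cell members outside the immunoglobulin genes had a median of -0.41. Pooled transcript values do not separate the number of cells from the transcript per cell. A possible explanation that remains, which was not tested, is fewer cells secreting IgM and some IgG classes in running mice. Whether 1 animal with many antibody-secreting cells caused it cannot be told apart from this, since there are 0 columns with values of single libraries.

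Outside the immunoglobulin genes 33 calls changed at least 2-fold, 17 higher and 16 lower. Of the 33, 14 had overlapping intervals and 6 a test statistic under 1.96 in size. The median of their mean FPKM was 3.33. Their authors' intervals had a median half-width of 50.2% of the FPKM, against 47.6% in expression-matched draws (p = 0.341, permutation test), so imprecise estimates cannot be told apart from real changes for the set: a p of this size excludes neither. Of the 103 calls outside immunoglobulin genes, 7 lay within 100 kb of a call in the opposite direction, against a mean of 1.54 in 10000 draws (p = 0.0092, permutation test): Hspa4l with Plk4 on chromosome 3, and Trem3, Treml4, B430306N03Rik, Treml1 and Nfya on chromosome 17. The genes on chromosome 17 lie together and the draws count genes, so the p does not measure an excess of separate loci. For these 7 genes, a different assignment of fragments between neighbours in the 2 groups may be the source. Local regulation by running was not tested. For the other large changes neither a biological difference nor imprecise estimates can be excluded.

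Muscle, fat, tendon and glucocorticoid-responsive genes were enriched among the higher calls, while neutrophil genes had a median of -0.17 with no call; the p-values that follow treat genes as independent and describe the pooled values of these libraries, not the spread between mice. A lower share of blood cells alone would raise all non-blood lists alike only if blood cells do not express the list genes, which was not tested. The 10 lists differed (p = 5.0e-05, permutation test over 130 genes), with interquartile ranges of 0.22 to 0.68 for adipocyte and -0.09 to 0.13 for chondrocyte genes. More muscle of every fibre type is argued against by the slow fibre genes, whose median lay 0.29 below that of the skeletal muscle list (p = 0.000500, permutation test), with interquartile ranges of -0.03 to 0.04 and 0.18 to 0.44. Single slow fibre genes varied, with authors' deposited log2 folds from -0.34 (Myl3) to 0.38 (Mb). More fast muscle, fat or tendon on the bones of the running mice, or a change within those tissues, stays open. The skeletal muscle genes did not rise evenly, with authors' deposited log2 folds from 0.04 (Myl1) to 0.62 (Myh1). That list too was tested on the folds that had drawn attention to it. Whether the osteocyte median of 0.25 differs from the rise of the other non-blood lists was not tested. The same holds for the YAP and TAZ list, whose median of 0.19 was that of the pooled non-blood genes (0.19). The glucocorticoid list lay 0.19 above those genes (p = 0.0309, permutation test) but below the adipocyte list (0.39 against 0.54), and it was tested on the folds that had drawn attention to it, so a glucocorticoid-type response cannot be told apart from more fat or muscle.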
